A study of Mus musculus with 2 samples.

How the data were processed

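Single-cell RNA sequencing (10x Genomics Chromium, 3' chemistry) was deposited for 2 mouse libraries, 1 per group. Per the labels, live ZSGreen-positive cells were sorted from normal mammary gland (NEC, normal endothelial cells) and from EO771 tumors, a syngeneic mammary tumor line grown in the mammary fat pad of C57BL6/J mice (TEC, tumor endothelial cells). ZSGreen was switched on by tamoxifen through the endothelial Cdh5 promoter in these mice. Per the submitters' processing notes, Cell Ranger 2.0.2, STAR 2.5.1b, Seurat and the mm10 build were used; their settings are not given in the sources used here.

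The deposited table holds UMI counts, whole numbers per gene and cell with no normalization, for 13774 genes and 2806 cells. Cells were given to libraries by the first part of their names: "control" was taken as NEC and "tumor" as TEC, and the first of these rests on the word alone. No column was left over. Most genes listed for a library were present in at least 5 of its cells, and a gene without counts in 1 library was listed there at 0, so 11386 genes had counts in both libraries; no fold is given for the others. The TEC library has exactly 1000 cells, the shallowest with 6376 UMIs, while the shallowest of the 1806 NEC cells has 1157 UMIs. This depth gap, or a UMI cut behind it, can set the shares of cells given for the libraries.

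Cells with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, which removed 5 NEC cells and 0 TEC cells. Scrublet in scanpy 1.11.5 (expected rate 0.8% per 1000 cells) called 7 NEC and 3 TEC cells, which were removed, and 1794 NEC and 997 TEC cells remained. Scrublet left in place tumor cells that held transcripts of both T cells and macrophages; their values stand beside the comparisons. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbors and Leiden clustering at resolution 0.8 gave 13 clusters, without integration of the libraries (anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, Python 3.11.15).

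Markers of 19 cell classes were fixed before the data were examined, as were the gene lists, the cell filter, the rule for named genes and the other settings to be run. The scoring of markers was not. A cluster was called "X-like" where at least 3 markers of a class were present in at least 10% of its cells, stood at 50 CPM (UMIs scaled to a common total) or more, and were at least 2-fold above the other cells with 5 CPM added to both. This was the last of 3 scoring rules tried, and it was settled after the clusters had been seen. The first rule lacked the CPM minimum and named cluster 5 endothelial-like on low levels of these markers, against its leading genes; the second used cells thinned to 1000 UMIs for detection and named cluster 9 T or NK-like. The minimum kept cluster 5 (0.223% of NEC and 20.96% of TEC cells) and cluster 8 (0.669% of NEC and 7.62% of TEC cells) without a name.

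The planned comparison of endothelial-like cells could not be made because no cluster was given that name. In its place, and chosen after the clusters had been seen, UMIs were summed per library over the macrophage or monocyte-like cells, a T or NK-like cluster and a dendritic-like cluster with at least 20 cells of each library. With 1 library per group there is no test. For each gene with at least 50 UMIs over both sums, the ratio of CPM (TEC over NEC) is given with an exact Clopper-Pearson 95% interval conditional on the gene's total. CPM has exact Poisson intervals and shares have exact binomial ones. All intervals cover counting error only, not differences between animals or libraries. A gene met the size rule when its ratio was at least 2 in either direction and the interval excluded 1; a sum of 0 was set to 3 counts to give a bound. The named genes are the 12 with the highest lower bound and the 12 with the lowest upper bound, leaving out mitochondrial, ribosomal protein, hemoglobin and immunoglobulin genes; genes of the fibrinolytic and TGF-beta systems were named in advance whatever their values. For each of 18 fixed lists with at least 5 measured genes, the median log2 ratio was placed among 10000 random lists of the same size matched on expression. A further 5 lists were chosen after the clusters had been seen. The result of 1 gene named in advance is not reported here.

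The size rule was tested on simulated data, counts drawn from the pooled gene levels with 200 genes changed. At the depths of the macrophage, T or NK and dendritic comparisons, 6662, 2324 and 1493 genes were tested. Of the genes changed 3-fold, the rule recovered 98.9% of 95, 97.0% of 99 and 95.4% of 87. It recovered 100% of 6-fold changes in each, and 0.603%, 0.282% and 1.36% of unchanged genes met it. The simulated counts held counting error only, with no spread between cells or libraries. These rates therefore do not bound wrong calls in the real sums, where 1 cell can hold much of a gene's UMIs. Of 100 random lists of 15 genes, 4, 10 and 6 lay outside the central 95% range in those 3 simulations, against a nominal 5, so a percentile near those limits carries little weight. Alternatives were other cell filters, Scrublet calls kept, a TMM-type scaling, the mean of per-cell CPM, other UMI minimums, Leiden resolutions 0.4 and 1.5 and, added after seeing the data, the other scoring rules and 3 narrower sets of macrophage or monocyte-like cells. The TMM-type scaling moved log2 ratios by -0.24, -0.23 and -0.07 in the macrophage, T or NK and dendritic comparisons. Gene positions are from GENCODE vM21 (GRCm38, the same assembly as mm10).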

Results

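The study set endothelial cells of the normal mammary gland against those of EO771 tumors, and its title names a TGF-beta-driven fibrinolytic pathway in endothelial subtypes. The table used here held 5228289 UMIs in 1806 cells of the NEC library and 16444540 UMIs in 1000 cells of the TEC library. Kept cells had a median of 2259 UMIs and 801.5 genes in NEC and 8594 UMIs and 2212 genes in TEC, with 3.21% and 1.59% mitochondrial UMIs. There was 1 library per group, so no difference has a replicate check, no p-value is given, and every interval is a 95% counting interval.

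Leukocytes made up most of both libraries, and no cluster met the rule for endothelial-like cells. In NEC, B or plasma-like cells were 37.5% of cells (95% interval 35.2 to 39.7), T or NK-like cells 37.6% (35.3 to 39.9) and macrophage or monocyte-like cells 17.1% (15.4 to 18.9); with the stricter cell filter these were 8.54%, 46.0% and 31.5%. In TEC, macrophage or monocyte-like cells were 59.8% (56.7 to 62.8), T or NK-like cells 4.71% (3.48 to 6.22) and B or plasma-like cells 0.401% (0.109 to 1.02). The T or NK-like share of TEC lay between 9.90% and 10.6% under 5 other settings, outside that counting interval. Fibroblast-like cells (Dcn, Col1a2) were 4.07% of NEC and 0.502% of TEC cells, and epithelial-like cells (Krt18, Epcam) 1.73% and 0.100%. Endothelial-like clusters held 0 of 1794 NEC and 0 of 997 TEC cells; whole clusters were named, so single endothelial cells inside other clusters are not counted. These contents differ from the sort that the labels describe, so the values that follow are not values of endothelial cells. The shallowest TEC cell had 6376 UMIs, a gap in depth that can set these shares, and most clusters came almost wholly from 1 library, so that cell type and library cannot be told apart for them.

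**Figure D1:**
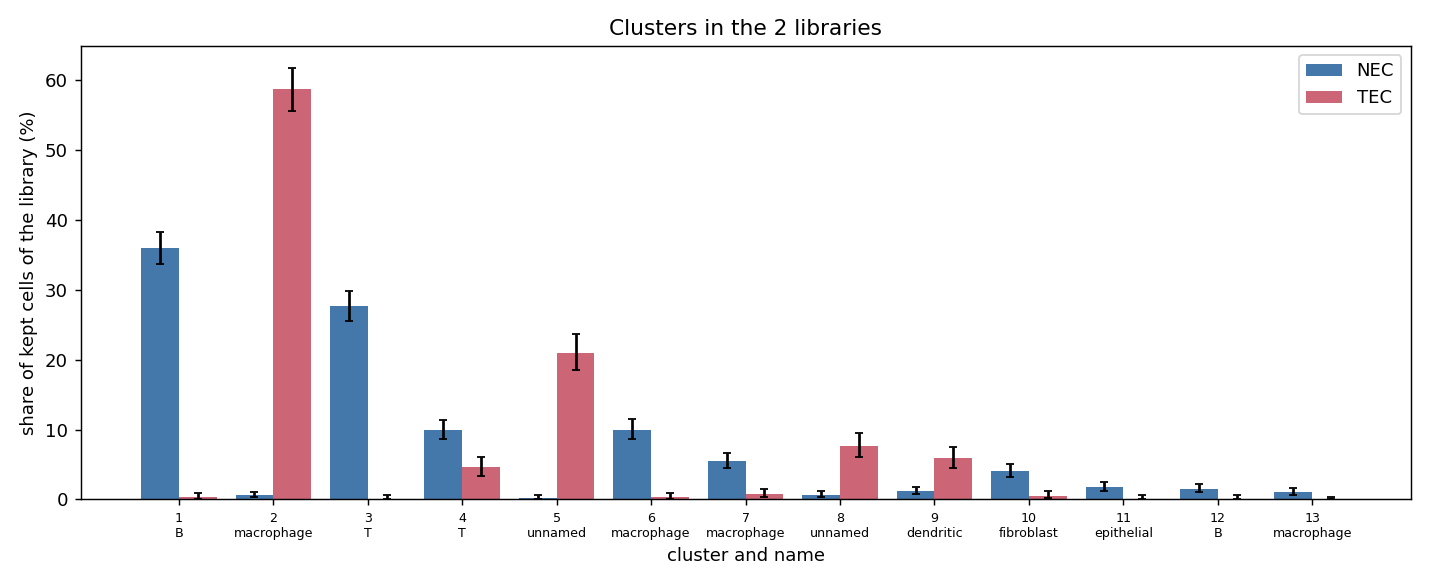
Share of kept cells (%) in each of 13 clusters for the NEC library (blue, 1794 cells) and the TEC library (red, 997 cells), with exact binomial 95% intervals as bars. Cluster 2, macrophage-like, held 58.8% of TEC and 0.557% of NEC cells, while clusters 1 (B-like) and 3 (T-like) held 36.0% and 27.6% of NEC cells.

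Cluster 5 held 209 TEC and 4 NEC cells and kept its number. It was led by Rhox5, a homeobox gene, Nppb, Cav1, Cald1 and Tex19.1, and its TEC cells had a median of 37079 UMIs. Rhox5 stood at 636.6 CPM (620.5 to 653.0) in it and was listed at 0 for the whole NEC library. Ptprc, the pan-leukocyte gene CD45, stood at 8.46 CPM in it against 241.5 CPM in cluster 2 of the same library. Its TEC cells held 165.4 CPM of pan-endothelial markers (14 genes; 113.8 CPM without the 6 cells richest in them), 254.4 CPM of fibroblast markers (10 genes), 144.9 CPM of epithelial or mammary tumor markers (11 genes), 137.1 CPM of pericyte or smooth muscle markers (3 genes) and 2837 CPM of proliferation markers (15 genes). In macrophage or monocyte-like cells of the same library these sums were 65.6, 16.4, 19.9, 6.05 and 1044 CPM, in that order. Pan-leukocyte markers (5 genes) held 137.2 CPM in cluster 5 and 4541 CPM in those macrophage or monocyte-like cells. Whether cluster 5 holds tumor cells was not tested. Under the scoring rule without a CPM minimum this cluster was named endothelial-like, which gave a share of 20.96% in TEC and 0.223% in NEC.

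Plat, the tissue plasminogen activator gene (chromosome 8, 22757727 to 22782844), was at 29.5 CPM in NEC and 24.1 CPM in TEC over all cells, a ratio of 0.817 (0.676 to 0.991), and reached 591.1 CPM in NEC fibroblast-like cells, so the sums cover different cell types. Cluster 5 held 57.1% of the TEC UMIs, with Plat at 38.1 CPM and Plaur at 230.1 CPM. Plau, the urokinase gene (chromosome 14, 20836660 to 20843385), was at 5.20 and 4.95 CPM, a ratio of 0.952 (0.609 to 1.53). Plaur, the urokinase receptor gene (chromosome 7, 24462484 to 24475968), was 2.72-fold higher in TEC over all cells (2.51 to 2.95) and 2.13-fold higher within macrophage or monocyte-like cells (1.91 to 2.38). Among genes of the TGF-beta system, Tgfbi (chromosome 13, 56609523 to 56639562), which encodes a matrix protein induced by TGF-beta, was 2.68-fold higher in the TEC macrophage or monocyte-like cells (2.49 to 2.90). In those cells the ratio was 0.923 for Tgfb1 (0.836 to 1.02), 0.650 for Tgfbr1 (0.459 to 0.935), 0.865 for Tgfbr2 (0.585 to 1.31), 1.39 for Eng (0.62 to 3.68) and 0.964 for Smad7 (0.734 to 1.28). Tgfbr3 had 3 and 4 UMIs there and a ratio of 0.310 (0.0524 to 2.11).

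**Figure D2:**
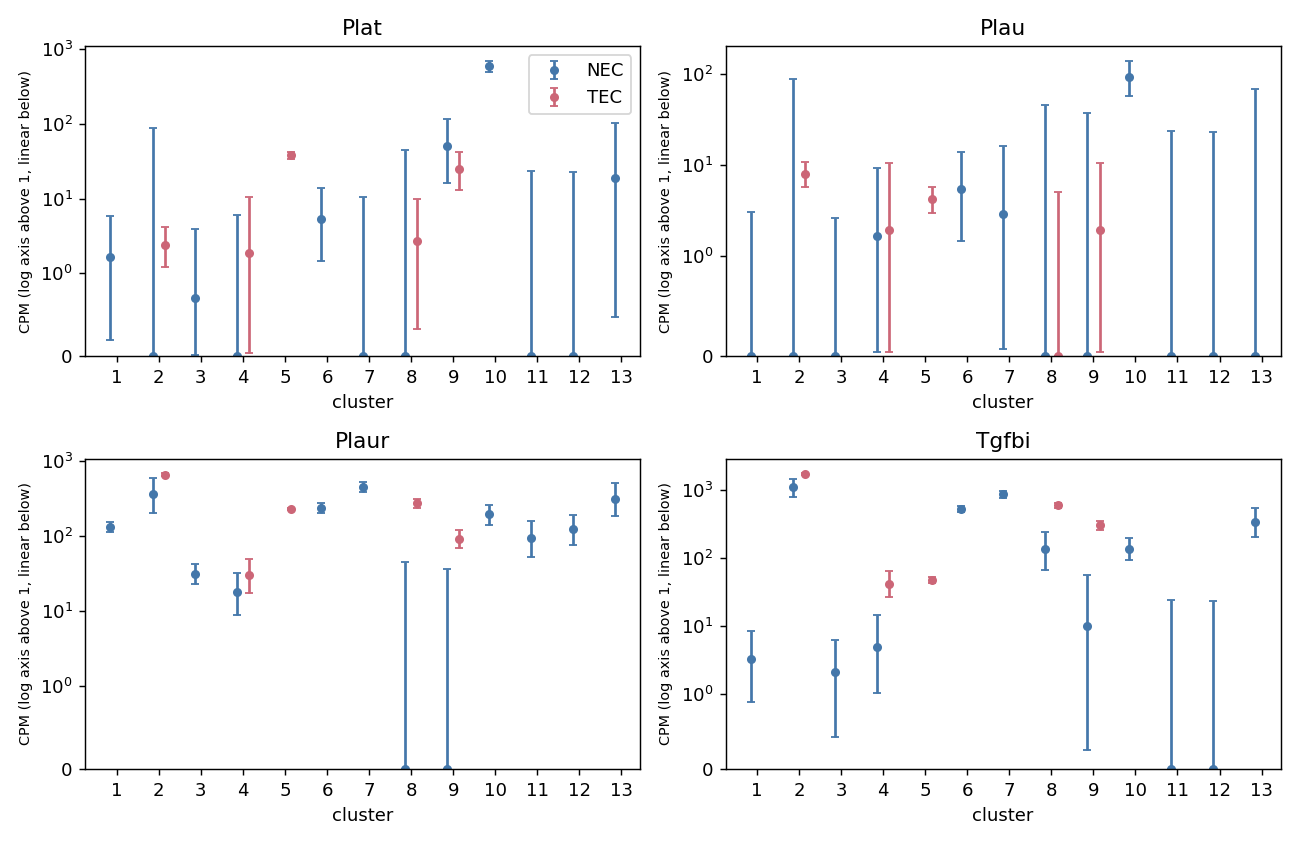
CPM of Plat, Plau, Plaur and Tgfbi in each cluster with at least 10 cells of a library, NEC in blue and TEC in red, with exact Poisson 95% intervals as bars; the axis is logarithmic above 1 CPM and linear below. Plat stood at 591.1 CPM in cluster 10 of NEC and Tgfbi at 1679 CPM in the TEC macrophage or monocyte-like cells.

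Macrophage or monocyte-like cells of TEC had higher levels of interferon response and glycolysis genes than those of NEC. The 596 TEC cells were nearly all in cluster 2 and the 307 NEC cells mostly in clusters 6, 7 and 13, so the comparison sets these clusters against each other. Of 6683 genes compared, 1509 met the size rule as higher in TEC, 440 as lower and 4734 as neither; with the TMM-type scaling 1035 were higher and 660 lower. Among the named genes, Ms4a7, a macrophage membrane protein gene, was 168-fold higher (57.3 to 813), Ifit3 92.8-fold (36.2 to 341), Ly6a 57.2-fold (35.7 to 98.3) and Ms4a4c 37.1-fold (26.2 to 54.3), and Ifit2 at least 49.8-fold and Mmp14, a membrane matrix metalloproteinase gene, at least 38.8-fold. Cd72, Scimp, Ccl8, Ifit1bl1 and Ms4a6d completed that group with Gzmb. Ccl8 was present in 8.39% of the TEC cells, and 1 cell held 38.9% of its TEC UMIs. Lyz1 was 120-fold lower in TEC (92.3 to 158), Ltc4s, for leukotriene C4 synthase, 64.1-fold lower (38.6 to 114), and Fcrls 27.2-fold lower (20.8 to 36.1). In TEC, 1 cell held 52.5% of the 59 Lyz1 UMIs, 31.25% of the 16 for Ltc4s and 30.2% of the 63 for Fcrls. Lyve1, a hyaluronan receptor gene, was at least 84.7-fold lower, and Fcna, Fgfr1, Cd209d, C4b, Fxyd2, Ptgs1, Ear2 and Tmem176b also fell in that group. Of these, 2 of the 12 higher and 6 of the 12 lower genes also define 1 of the clusters, which fixes part of the difference.

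The Gzmb difference did not come from the class as a whole. Of the TEC macrophage or monocyte-like cells, 92 of 596 (15.4%, 12.6 to 18.6) held a UMI of Cd3e, Cd3d or Cd3g, T-cell receptor complex genes, against 11 of 307 in NEC (3.58%, 1.80 to 6.32). Gzmb stood at 558.7 CPM in those 92 cells and at 5.54 CPM in the other 504, and Nkg7 at 614.5 and 2.41 CPM. Without cells holding a Cd3 UMI, 1397 genes were higher and 447 lower, and 1303 and 387 of these were shared with the full comparison; the other 11 higher named genes and all 12 lower ones met the size rule again.

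Among the fixed lists, interferon response genes had the median farthest from 0: 27 of 29 measured members were higher in TEC and 0 lower, with a median log2 ratio of 2.28 at percentile 100 of random lists. Isg15 was 22.4-fold higher (18.3 to 27.7), Irf7 28.6-fold (21.7 to 38.4) and Rsad2 14.6-fold (10.9 to 19.9). Of 25 glycolysis and hypoxia genes, 14 were higher, 1 lower and 10 neither (median 1.32, percentile 99.99): Pkm, for pyruvate kinase, was 4.41-fold higher (4.01 to 4.86) and Ldha 3.02-fold (2.72 to 3.36), while Hk2 was 4.11-fold lower (3.43 to 4.91). Of 19 antigen presentation genes, 9 were higher and 1 lower (median 0.81, percentile 98.6); Psmb9 and B2m, of the class I pathway, were 4.45-fold (3.49 to 5.76) and 2.70-fold (2.61 to 2.80) higher, and Cd74, the class II invariant chain gene, was 2.66-fold lower (2.60 to 2.72). Of 12 fibrinolysis and coagulation genes, 6 were higher and 2 lower (median 1.00, percentile 99.4), among them Procr at 5.30-fold (2.91 to 10.7) and Anxa2 at 2.52-fold (2.31 to 2.76) higher and Pros1 at 5.32-fold lower (3.30 to 8.62). Of 6 Notch genes, 3 were lower and 0 higher (median -1.03, percentile 0.1), with Notch1 5.09-fold lower (3.34 to 7.79). The antigen presentation median moved inside the range of random lists with Scrublet calls kept (0.75), and the fibrinolysis and coagulation median without the Ace and Treml4 cluster (0.91). With Scrublet calls kept, the 88 cells of cluster 8 were also named macrophage or monocyte-like, so the class compared changed as well.

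Vascular tone genes (6 measured, 2 higher, 3 lower, median -0.89) and tip cell and angiogenesis genes (7 measured, 2 higher, 3 lower, median -0.41) had low medians with members on both sides, and both medians turned positive when NEC cells with fewer than 4000 UMIs were left out. TGF-beta ligands, receptors and Smads had 2 of 11 members higher and 0 lower (median 0.23), Inhba being 20.6-fold higher (11.1 to 43.1). The TGF-beta and BMP response list had 3 of 17 higher and 2 lower (median 0.26), with Fn1 8.33-fold lower (7.60 to 9.13). Inhba also leads cluster 2 and Fn1 cluster 13, which fixes part of their differences. Medians of the other fixed lists with at least 5 measured genes lay within the central 95% of random lists: basement membrane and extracellular matrix 0.99, capillary fatty-acid handling 0.85, venous and leukocyte adhesion 0.61, proliferation 0.37, unfolded protein and translation 0.30, endothelial-to-mesenchymal transition 0.25 and immediate early and dissociation 0.18. The arterial and the junction and barrier lists had 2 and 4 measured genes and no median. The median over all 6683 genes was 0.38.

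**Figure D3:**
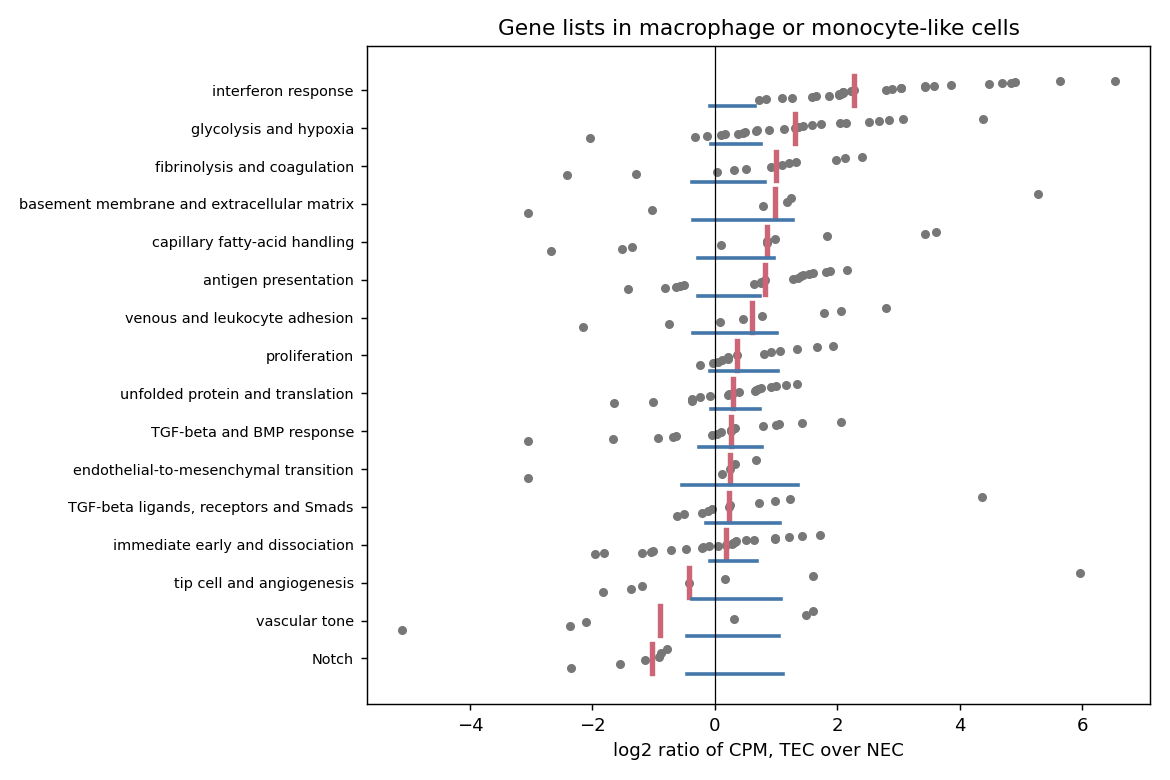
Log2 ratio of CPM (TEC over NEC) of each measured gene (gray points) in the fixed lists, for 596 TEC and 307 NEC macrophage or monocyte-like cells, with each list's median (red) and the central 95% range of medians of 10000 matched random lists (blue). The interferon response median, 2.28, and the Notch median, -1.03, lie outside that range.

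The T or NK-like cluster shared by both libraries (cluster 4, led by Tnfrsf4, Rora and Il2rb) had higher proliferation genes and lower TGF-beta response and immediate early genes in TEC. It held 178 NEC and 46 TEC cells, and whether these are the same kinds of lymphocytes was not tested: Il5 and Calca had counts in NEC only and Gzmc, Gzmd, Gzme, Gzmf and Gzmg in TEC only. Of 2303 genes compared, 514 met the size rule as higher in TEC, 287 as lower and 1502 as neither; with the TMM-type scaling 356 were higher and 390 lower. Gzma and Gzmb, granzymes of cytotoxic cells, were 26.4-fold (20.1 to 35.4) and 25.6-fold (19.3 to 34.7) higher, and Birc5, a mitotic gene, 42.1-fold (14.02 to 207). Ube2c, Ifitm3, Ifitm1 and Il1r2 were also among the 12. The remaining 5 lean on few cells or on other cell types: 1 cell held 88.5% of the S100a9 and 80.2% of the S100a8 UMIs in TEC, 54.5% of the Ccl3, 44.9% of the Thbs1 and 40.9% of the Spp1 UMIs, and Lyz2, a myeloid gene, stood at 157 CPM there against 26.1 CPM in NEC. Pmepa1 and Ski, of the TGF-beta response list, were 10.0-fold (5.69 to 19.3) and 7.78-fold (4.16 to 16.1) lower, and S1pr1, a receptor for exit from tissue, 10.996-fold (5.96 to 22.5) lower. Fos was 5.17-fold lower (3.90 to 6.97), and Jmy, Tmem64, Ramp3, Samd11, Dusp10, Tcp11l2, 5430421N21Rik and Prkca completed the group. Of the 12 higher and 12 lower genes, 2 and 1 also define a cluster.

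Of 15 proliferation genes in this cluster, 14 were higher and 0 lower (median log2 ratio 2.38, percentile 100), such as Top2a at 9.14-fold (4.72 to 19.8). Of 10 interferon response genes, 6 were higher and 1 lower (median 2.10, percentile 100), and of 11 glycolysis and hypoxia genes 9 were higher (median 1.52, percentile 99.95). Of 12 TGF-beta and BMP response genes, 7 were lower and 1 higher (median -1.06, percentile 0.03); Smad7, an inhibitor of TGF-beta signaling that the pathway induces, was 4.20-fold lower (3.15 to 5.69). Of 18 immediate early and dissociation genes, 13 were lower and 0 higher (median -1.42, percentile 0), Junb being a member of both lists. Of 7 fibrinolysis and coagulation genes, 5 were higher (median 1.71, percentile 99.9), with Anxa2 6.47-fold (4.95 to 8.59). The other higher members were S100a10, Anxa5, Plgrkt and Thbs1, and 1 cell held 44.9% of the Thbs1 UMIs in TEC. Plat, Plau and Plaur were not among the 7 measured, so this median says nothing of the plasminogen activators or the urokinase receptor. Antigen presentation (median 0.18) and unfolded protein and translation (median 0.51) lay within the range of random lists. The counts of genes in this cluster changed by over 1.5 times with the stricter cell filter, and the higher count also with the clustering resolution. The glycolysis and hypoxia median moved inside the random range (0.78) with marker detection in thinned cells. That setting also named the 80 cells of cluster 9 T or NK-like, so other cells entered the comparison.

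The dendritic-like cluster (cluster 9, led by Ccl22, Il12b and Tbc1d4) had higher interferon response genes in TEC. It held 21 NEC cells with 100043 UMIs and 59 TEC cells, and its name rests on Flt3, Ccr7 and Batf3, while 3 T or NK markers were also raised in it. Of 1493 genes, 290 met the size rule as higher in TEC, 87 as lower and 1116 as neither; at resolution 0.4, where cluster 8 was dendritic-like too, 556 were higher and 138 lower, and the stricter filter left no such shared cluster. Ifi27l2a was at least 63.9-fold higher, Ifitm1 at least 32.5-fold, Ifitm3 28.3-fold (12.97 to 77.4), Irf7 28.4-fold (7.79 to 235) and Isg15 18.3-fold (7.11 to 67.7); Ly6c2, Plac8, Areg and Nkg7 were also among the 12, as was Lyz2, a gene of macrophages, 53.9-fold higher (14.9 to 446) and present in 72.9% of TEC cells at 1078 CPM. Of the other 2, 1 cell held 62.9% of the TEC UMIs of Gzmb and 82.9% of those of Spp1. Hspa1a, a heat shock gene, was 6.53-fold lower (4.63 to 9.22), Mt2 and Mt1, metallothioneins, 5.45-fold (4.10 to 7.24) and 4.17-fold (3.43 to 5.05) and Nr4a3 4.77-fold (3.44 to 6.61); Mreg, Bmp2k, Clu, H2-M2, Gpr137b and Malat1 followed. The last 2 were Gm10116 and Gm11808. Whether reads of similar genes were given to them was not tested. In NEC, 1 cell held 49.4% of the 79 Hspa1a UMIs and 1 cell held 40.8% of the 103 Mt2 UMIs. Hspa1a was present in a smaller share of NEC cells than of TEC cells. The Hspa1a and Mt2 folds therefore lean in part on single NEC cells. Of the 12 higher and 12 lower genes here, 2 and 1 also define a cluster. Of 14 interferon response genes 11 were higher and 0 lower (median 2.97, percentile 100), of 11 glycolysis and hypoxia genes 7 were higher and 1 lower (median 1.46), of 7 fibrinolysis and coagulation genes 4 were higher (median 1.60, percentile 98.8, but 1.09 and inside the random range as the mean of per-cell CPM), and of 15 immediate early and dissociation genes 3 were lower and 1 higher (median -0.38, percentile 0.55, but 0.35 at resolution 0.4). Plat, Plau and Plaur were not among the 7 fibrinolysis and coagulation genes measured here. Antigen presentation, TGF-beta and BMP response and unfolded protein and translation had medians of 0.32, -0.11 and 0.62, within the range of random lists.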

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

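The tests in this part were chosen after the results they bear on had been seen, except the test of doublets with T cells, whose prediction was written before it was run.

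Some genes of the fixed lists met the size rule in opposite directions in 2 cell classes. The log2 ratio (TEC over NEC) was 1.21 for Btg2, 1.42 for Fos, 1.26 for Irf1, 1.60 for Ramp3 and 1.73 for Socs3 in macrophage or monocyte-like cells, and -1.22, -2.37, -1.09, -3.14 and -2.09 in the T or NK-like cluster, where Ramp3 turned to 0.51 with marker detection in thinned cells. The difference between the classes was not tested, since each group has 1 library.

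No cluster was named endothelial-like, although the labels describe a sort for an endothelial reporter. Removal of the markers by the gene filter is argued against for the tumor library, where 12 of the 15 pan-endothelial markers had counts. In the normal-gland library 8 had counts, Cdh5 and Kdr not among them, and that number does not decide. Of the 12004 genes with counts there, 15 were in 1 to 4 cells. A filter near 5 cells could hide markers of a few endothelial cells, which stays open. Markers present in most cells of even the smallest cluster, of 19 cells, would pass it. The filter is thus argued against as the reason why no cluster was named. The name of the deposited table includes "negs", a word that the labels do not explain. Whether the table holds the reporter-negative fraction of the sort cannot be told apart from a sort that failed, because 0 reporter transcripts were in the table and nothing shows that the reporter was in the reference used. The study's groups give no biological explanation of this pattern, and none was tested.

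T and NK genes were higher in tumor macrophage or monocyte-like cells. Free RNA with the makeup of the T or NK-like cluster is argued against as the whole source: the markers' levels, as a share of their level in that cluster, differed by 57.7 times between Cd3g (14.994%, 12.996 to 17.3) and Gzma (0.26%, 0.176 to 0.371), leaving aside Il7r, which these cells express without Cd3 at 193.9 CPM. Doublets with T cells are a candidate explanation: without the cells holding a Cd3 UMI, Gzmb and Nkg7 together stood at 3.48% (2.38 to 4.92) of their CPM in all of these cells. The Gzma gap bears on doublets as well, since a random draw of that cluster's cells would carry Gzma and Cd3g at the same share. It therefore does not separate such doublets from free RNA. In the 69 cells with at least 3 Cd3 UMIs, Lyz2 stood at 5010 CPM against 9220 CPM in cells without Cd3. The median depth of these 69 cells was 9735 UMIs, against 7426 in cells without Cd3 and 9364 in TEC cells of the T or NK-like cluster. No TEC cell had fewer than 6376 UMIs, so these medians leave out any shallower cells. The NEC cells of the T or NK-like cluster had a median of 2969 UMIs. Depth therefore cannot decide for or against doublets. TEC had 47 T or NK-like cells, yet 92 macrophage or monocyte-like cells with a Cd3 UMI, 69 of them with at least 3. NEC had 674 and 11, with 2 of the 11 at 3 or more. These counts run against random pairing of the cells listed. They do not exclude it, since any single T cells of the tumor below 6376 UMIs are missing. Pairs of attached cells, cells that took up T-cell material and a tumor difference in such contacts would look alike here and stay open.

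Ribosomal processed pseudogenes were lower in TEC in all 3 class comparisons. The parents' median log2 ratios were also below 0: -0.51, -0.24 and -0.28 in the macrophage, T or NK and dendritic comparisons. A fall of ribosomal protein transcripts in tumor cells is argued against only as the whole source. The median over pairs of the pseudogene's log2 ratio minus its parent's was -1.16 in the comparison where it lay nearest to 0. Reads given to pseudogenes more often in the normal-gland library stay open as an explanation: the pseudogene was lower relative to its parent in every comparison in 100% of the measured pairs, which restates the pattern and is no test of its cause.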

How the results depend on the processing

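With 1 library per group, no replicate was left out. No paired analysis was possible because each group has 1 library. Also not run were proliferating endothelial clusters left out, cells without leukocyte markers and clusters weighted to 1 mix, since no endothelial cluster was named. The scoring rules and the sets of cells chosen by UMIs, Cd3 or the Ace and Treml4 cluster were added after seeing the data. The cause was not tested unless given. Of 648 alternative values of named genes, 647 kept their call and 1 changed sign, leaving out genes without a value: with the stricter filter 22 of 24 macrophage or monocyte-like, 15 of 24 T or NK-like and 0 of 24 dendritic-like genes had one, and 19 of 24 macrophage or monocyte-like genes with NEC cells of at least 4000 UMIs; of 254 of list medians outside the random range, 234 stayed outside, 14 moved inside and 6 changed sign.

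The endothelial-like share was 0 in both libraries under all cell filters and resolutions run, and 0.223% of NEC and 20.96% of TEC cells under the first scoring rule, without a CPM minimum; under the second, with detection in thinned cells and no CPM minimum either, it was 0. Genes higher and lower in macrophage or monocyte-like cells were 762 and 181 with at least 200 UMIs, where fewer genes enter, and within 1.5 times the reported counts otherwise. In the T or NK-like cluster they were 217 and 161 with the stricter cell filter, 930 and 533 with at least 20 UMIs, 128 and 80 with at least 200 UMIs; the higher count was 332 at resolution 0.4, 341 at 1.5 and 814 with marker detection in thinned cells, which adds cluster 9. In the dendritic-like cluster they were 66 and 23 with at least 200 UMIs and 556 and 138 at resolution 0.4, where cluster 8 is dendritic-like too, and the lower count was 154 with at least 20 UMIs; the stricter filter left no such shared cluster.

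The macrophage or monocyte-like share was 31.5% of NEC with the stricter filter, and 54.4% of TEC without a cell filter and 54.5% at resolution 1.5. The T or NK-like share was 46.0% of NEC with the stricter filter, and 10.0% of TEC without a filter, 9.90% with the stricter one, 10.2% with Scrublet calls kept, 10.0% at resolution 1.5 and 10.6% with detection in thinned cells. At resolution 1.5, 52 of the 69 macrophage or monocyte-like cells with at least 3 Cd3 UMIs moved to it. The B or plasma-like share of NEC was 8.54% with the stricter filter, which removes shallow cells. Under that filter, 84 of 85 cluster 8 cells also counted as macrophage or monocyte-like.

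In macrophage or monocyte-like cells the tip cell and angiogenesis median was 0.17 with the stricter filter. It was 0.15 with NEC cells of at least 4000 UMIs. With the stricter filter 84 of 85 cluster 8 cells were also named macrophage or monocyte-like, and 537 of 588 cluster 2 cells kept that name. The class compared therefore changed as well. The vascular tone median was 0.79 with that filter, 0.67 with NEC cells of at least 4000 UMIs and 0.91 without the Ace and Treml4 cluster. The fibrinolysis and coagulation median moved inside the random range without that cluster (0.91), and in the dendritic-like cluster as the mean of per-cell CPM (1.09). The antigen presentation median moved inside it with Scrublet calls kept (0.75), as did the T or NK-like glycolysis and hypoxia median with detection in thinned cells (0.78) and the lipid and lysosome median with the stricter filter (0.65) and at resolutions 0.4 (0.76) and 1.5 (0.80). The other 7 of the 14 were tip cell and angiogenesis medians of macrophage or monocyte-like cells, from -0.66 to -0.26. The immediate early median of the dendritic-like cluster was 0.35 at resolution 0.4, and the Ramp3 log2 ratio of the T or NK-like cluster 0.51 with detection in thinned cells.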

Other observations

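The lists, cells and genes in this part were chosen after the data had been seen. Of 16 chemokines measured in macrophage or monocyte-like cells, 11 were higher in TEC and 3 lower (median log2 ratio 2.17, percentile 100): Ccl4 was 35.0-fold higher (24.5 to 52.0) and Ccl12 26.3-fold (17.6 to 41.1), and Ccl24 5.85-fold lower (5.12 to 6.70). Of 9 tissue-resident macrophage genes, 7 were lower and 0 higher (median -2.44), with Folr2 5.41-fold lower (4.20 to 6.99). Of 16 lipid and lysosome genes, 10 were higher and 3 lower (median 1.31); Gpnmb and Spp1 were 19.5-fold (10.6 to 40.9) and 16.4-fold (13.3 to 20.5) higher, while Apoe was 6.02-fold lower (5.76 to 6.30). Retnla stood at 18869.5 CPM in NEC macrophage or monocyte-like cells and was listed at 0 in the whole TEC library; Mmp13 stood at 163.6 CPM in those of TEC and was listed at 0 in NEC. Of 13 T-cell activation and checkpoint genes, 12 were higher (median 3.46); without the cells holding a Cd3 UMI 4 were still measured and 3 of them higher. Naive T-cell genes had a median of 0.97. Among the genes given here, Ccl12 also leads cluster 2, Ccl24, Folr2 and Retnla lead cluster 6 and Apoe leads cluster 13, which fixes part of their differences.

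In the T or NK-like cluster, 8 of 13 activation and checkpoint genes were higher and 1 lower (median 1.52): Tnfrsf9 was 4.35-fold (3.50 to 5.46) and Ctla4 3.99-fold (2.79 to 5.83) higher, and Ccl5 2.57-fold lower (2.34 to 2.82). Of 10 naive T-cell genes, 6 were lower (median -1.19), such as Lef1 at 3.31-fold (2.07 to 5.48), and 4 of 7 lipid and lysosome genes were higher (median 1.31, inside the random range with the stricter filter and at both other resolutions). Gzmc, a granzyme gene, stood at 2458 CPM in TEC and was listed at 0 in NEC. In the dendritic-like cluster, 6 of 8 lipid and lysosome genes and 5 of 6 activation genes were higher, and chemokines had a median of 0.42. Spp1 and Gzmb were among these higher genes, with 82.9% and 62.9% of their TEC UMIs in 1 cell. Lyz2 stood at 1078 CPM in TEC cells of this cluster. Cells holding macrophage or T-cell transcripts were not left out of it.

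Pan-endothelial markers took at least 0.3% of the UMIs in 6 TEC cells (0.602% of cells, 0.221 to 1.31) and 3 NEC cells (0.167%, 0.0345 to 0.488), all in cluster 5; the limit was set in a gap, as no other cell was above 0.155%. The 6 TEC cells held 78704 UMIs, with Cdh5 at 813.2 CPM (626.2 to 1038) and Pecam1 at 533.6 CPM (384.6 to 721.3), each in 6 of 6 cells. The 3 NEC cells held 4036 UMIs, and Cdh5 was listed at 0 for the whole NEC library. Cells this few show what is in them and do not stand for tumor endothelium.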
